A study of Drosophila melanogaster with 4 samples.

How the data were processed

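Heads of male flies were measured on 4 spotted cDNA arrays of 2 colours. Per the series' design text, each array carried RNA from its own pool of heads of drug-fed flies and its own pool of heads of flies on normal food, amplified to cRNA with T7 polymerase and labelled with Cy3 or Cy5, with the dyes swapped on 2 of the 4 arrays. Per the same text, the authors scanned the slides at 10 µm and quantified them with GenePix Pro 6.0. They normalized ratios in Acuity 4.0, leaving out spots with a raw intensity below 100. Spots were kept with a signal-to-noise ratio of at least 3, a regression R2 of at least 0.6, under 3% saturated pixels and no bad flag. The authors took features analysable on at least 3 arrays to one-class SAM 2.21 with 100 permutations. The genome build and the settings of the ratio normalization are not given in the sources used here.

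The deposited values, 1 column per array in the series matrix, were taken as log2 ratios. Per the labels they are ratio normalized, but neither the log base nor the direction nor any centring is stated. The values lie on both sides of 0, and log2 was taken as the usual scale of such ratios, so the log base remained an assumption. The medians of all deposited values were 0.74, 0.01, 0.18 and 0.59 on arrays 1 to 4. The scanner's own output was not used here.

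The direction was handled by a rule fixed before the data were examined, as were the test, the lists and the rule for naming genes. Values were read as channel 1 over channel 2, which the labels give as Cy5 and Cy3 on every array, and the sign was turned on arrays 3 and 4. The other reading, all columns already drug over normal food, would have become the main one if the rounding of the values had shown turned columns or if at least 6 control features had turned with the dye. Neither decided. Turned columns would have put values of arrays 1 and 2 on a grid of rounded linear ratios and those of arrays 3 and 4 on a grid of rounded inverse ratios. Within 0.05 grid steps, 13.0% and 28.7% of the usable values of arrays 1 and 2 lay on the linear grid, against 30.7% and 31.8% by chance. On the inverse grid lay 22.2% and 39.6% of those of arrays 3 and 4, against 35.5% and 37.0% by chance. These shares rest on 46, 261, 18 and 48 values, and none was clearly above chance. The check assumes that ratios were rounded before the log was taken, which is not stated. In that case arrays 1 and 2 would lie on the linear grid under either reading. They did not do so more than by chance, so this check could not have shown turned columns. No control features could be told apart in the probe table used here. The first reading therefore stayed and the direction was called unsettled.

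The table held 27648 spots. Neighbouring spots 1 and 2, 3 and 4 and so on were duplicates of 1 clone, since 7609 of 7609 such pairs with a gene name on both spots had the same gene, against 1 of 4716 pairs shifted by 1 spot. Duplicates were averaged into 13824 features. In the platform annotation 15116 spots had 1 gene symbol, 102 several and 12430 none, and 14894 of those with 1 symbol matched a current symbol through the Entrez gene number in RefSeq's table for Release 6. Features with several symbols or none were tested and not named, and no coordinates were used. Of the features, 7477 had no value on any array, 3863 on 1, 1504 on 2, 614 on 3 and 366 on 4. Between duplicate spots, r was 0.39, 0.61, 0.79 and 0.69 on arrays 1 to 4.

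Features with values on at least 3 arrays were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), as a one-class fit of the log2 ratio of drug over normal food against 0, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The deposited values were not normalized further. The SD given with a ratio is that over arrays. In the fit on the deposited values eBayes gave every feature the same variance, since differences between the arrays' medians made up most of the spread. The dye effect came from the same model with a dye coefficient of 1 or -1, so that it is the deviation of each orientation from their mean. With features reaching adjusted p under 0.05 in each direction, the named ones were the 12 with the largest mean ratio and the same sign on every array that measured them, filled up to 12 by lowest unadjusted p under 0.05. Up to 4 members of each list were named by the same order. CG10560, Cyp4p1, CG15096, Cyp6a20, GstD1, Cyp313a1, MFS14 and sowah came from the fill. Jhbp13, Dus1, CG6340, the P450 genes that did not pass, and the genes measured on fewer than 3 arrays other than calcium channels were chosen after their values were seen.

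For the 32 lists, clones of a gene were averaged per array, giving 515 genes over at least 3 arrays. The 8 lists with at least 5 measured genes were tested with cameraPR (limma) on moderated statistics, with a preset correlation of 0.01 and adjustment over the lists. An estimated correlation, bounded below at 0, and fry, a self-contained rotation test on genes measured on all 4 arrays, were run beside it. The other 24 lists had fewer than 5 measured genes, 5 of them none.

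The scripts were tested on simulated log2 ratios with the real pattern of missing values, array offsets and spread, drawn as independent normal values. With 20 of 980 features changed, the drug test recovered 37.5% of those changed by 1 on the log2 scale from uncentred values and 98.5% after centring, and 100% of those changed by 2 in both. With 200 changed, the share of false calls was 4.83% after centring.

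The alternatives were the other reading of the columns, a dye term, one-class SAM over all 16 sign flips, an unmoderated 1-sample test, a threshold of 0.10, features on all 4 or at least 2 arrays, centring, centring and scaling, array weights, a robust fit, clones averaged, and each array left out in turn. Combinations with centring, removal of the trend along the spots (lowess), a pooled list of enzymes and the estimated correlation with each array left out or the trend removed were added after seeing the data. Statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were also used.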

Results

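Gene expression was compared between heads of fruit flies fed ethosuximide, an anticonvulsant known as a blocker of T-type calcium channels, and heads of flies kept on normal food. Unmated Oregon-R males aged 10 to 11 days were held at 30 flies per vial for 3 days, with 3.48 mg/ml of the drug in the food of the treated vials. Each of 4 spotted cDNA arrays carried heads of drug-fed flies in 1 dye and heads of flies on normal food in the other, from separate pools of flies, so that each array was 1 biological replicate. On arrays 1 and 2 the drug sample carried Cy5, and on arrays 3 and 4 the dyes were swapped. After the authors' spot filters, 5095, 3169, 1101 and 812 of the 13824 clones (features) had a value on arrays 1 to 4. The 980 features measured on at least 3 arrays were tested, 528 of them with a single gene name, which together stood for 505 genes. The number of arrays limits the precision of every value below.

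The question was which transcripts of the head differed after feeding of the drug. On the deposited values 4 genes were higher with the drug and none was lower. CG6908 was the highest, at a log2 ratio of 2.29 ± 0.74 (SD, n = 3), or 4.90-fold. Jheh2, an epoxide hydrolase of juvenile hormone metabolism, was higher in both of its clones, by 1.53 ± 0.89 (SD, n = 4) and 1.37 ± 0.49 (SD, n = 3). The cytochrome P450 gene Cyp4e2 was higher by 1.48 ± 0.58 (SD, n = 4), and CG9445 by 1.49 ± 0.84 (SD, n = 3).

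These 5 features, from 4 genes, were the ones past limma's test among 980, each with a positive ratio on every array that measured it. The adjusted p was 1.64e-07 for CG6908, 0.000392 and 0.0243 for the Jheh2 clones, 0.00061 for Cyp4e2 and 0.0081 for CG9445. This fit gave every feature the same variance and treated it as known. These p values therefore do not measure how each feature varied over its own arrays. In the unmoderated test, which uses each feature's own spread, the adjusted p was 0.997 for each of the 5. On the deposited values that spread includes the differences between the arrays' medians. With each array centred on its median, the unmoderated adjusted p was 0.274 for the second Jheh2 clone and 0.229 for each of the others. On the deposited values 26 features had an unadjusted p under 0.05 in limma's test, 21 higher and 5 lower. After centring of each array 119 did (67 higher, 52 lower). The sign of every ratio rests on reading the deposited values as Cy5 over Cy3, the order in which the labels list the channels. The numerator is not stated, so the direction is unsettled, and "higher" and "lower" would change places if it were Cy3. If the dye-swap columns had already been turned to drug over normal food before deposit, 32 features, all higher, would pass on the deposited values. The median ratio over all 980 features would then be 0.40, so the offsets of the columns enter this count. After centring 0 would pass, and 86 had an unadjusted p under 0.05. Of the 5 features above, CG6908 alone would be among the 32, at 1.18. Its arrays would then disagree in sign. Its value on array 4, 1.66 under the reading used here, would turn negative, beside 3.11 and 2.10 on arrays 1 and 2. Cyp4e2 would be at 0.44 (limma adjusted p = 0.183), CG9445 at 0.13 (0.683) and the Jheh2 clones at 0.70 (0.066) and -0.09 (0.797).

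The deposited columns were not centred at 0. Over the tested features, their medians after turning were 0.74, 0.16, -0.24 and -0.63 on arrays 1 to 4. With each array centred on its median, which takes the ratios relative to the typical feature, 14 features passed, 12 higher and 2 lower, and the 5 features above were all among them. The split between higher and lower calls was therefore 5 to 0 on the deposited values and 12 to 2 after centring. The 14 features came from 11 genes and 2 clones with no gene name.

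After centring, CG10560 was higher by 1.19 ± 0.15 (SD, n = 3), Cyp4p1 by 0.90 ± 0.23 (SD, n = 3) and CG15096 by 0.88 ± 0.24 (SD, n = 3). Cyp6a20 was higher by 0.81 ± 0.31 (SD, n = 4), and GstD1, a glutathione S-transferase, by 0.80 ± 0.15 (SD, n = 3). In limma's test their adjusted p lay between 0.00458 for CG10560 and 0.0389 for GstD1. The lower genes were Cyp313a1, another cytochrome P450, at -0.80 ± 0.19 (SD, n = 4, limma adjusted p = 0.0151), and Jhbp13, named for binding juvenile hormone, at -0.61 ± 0.16 (SD, n = 4, limma adjusted p = 0.0453). On the deposited values none of these 7 genes passed. CG6908, Cyp4e2 and CG9445 had centred ratios of 2.20, 1.47 and 1.53, and the Jheh2 clones, in the order above, of 1.52 and 1.61.

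MFS14, a transporter of the major facilitator superfamily, and sowah, which encodes an ankyrin repeat protein, had ratios of 0.71 ± 0.42 (SD, n = 3) and 0.81 ± 0.49 (SD, n = 3) and did not pass on either set of values. Their centred means were 0.49 and 0.59, and for sowah the centred arrays went both ways, at -0.26, 0.42 and 1.60. Leaving out array 2 reduced the count on the deposited values from 5 to 1, CG6908, and leaving out array 3 reduced it to 3. After centring the count was 5 without array 1, 23 without array 2 and 7 without array 3, and none of the 5 or the 7 was lower. Of the genes that passed only after centring, CG10560, which had no value on array 1, kept its call whichever array was left out. CG15096, GstD1 and Cyp313a1 lost theirs without array 1 or 3, Cyp4p1 without array 1 or 4, Cyp6a20 without array 1, 3 or 4, and Jhbp13 whichever array was left out. Their ratios kept their sign in each case, from 0.67 to 1.02 for those higher and from -0.54 to -0.89 for those lower.

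**Figure D1:**
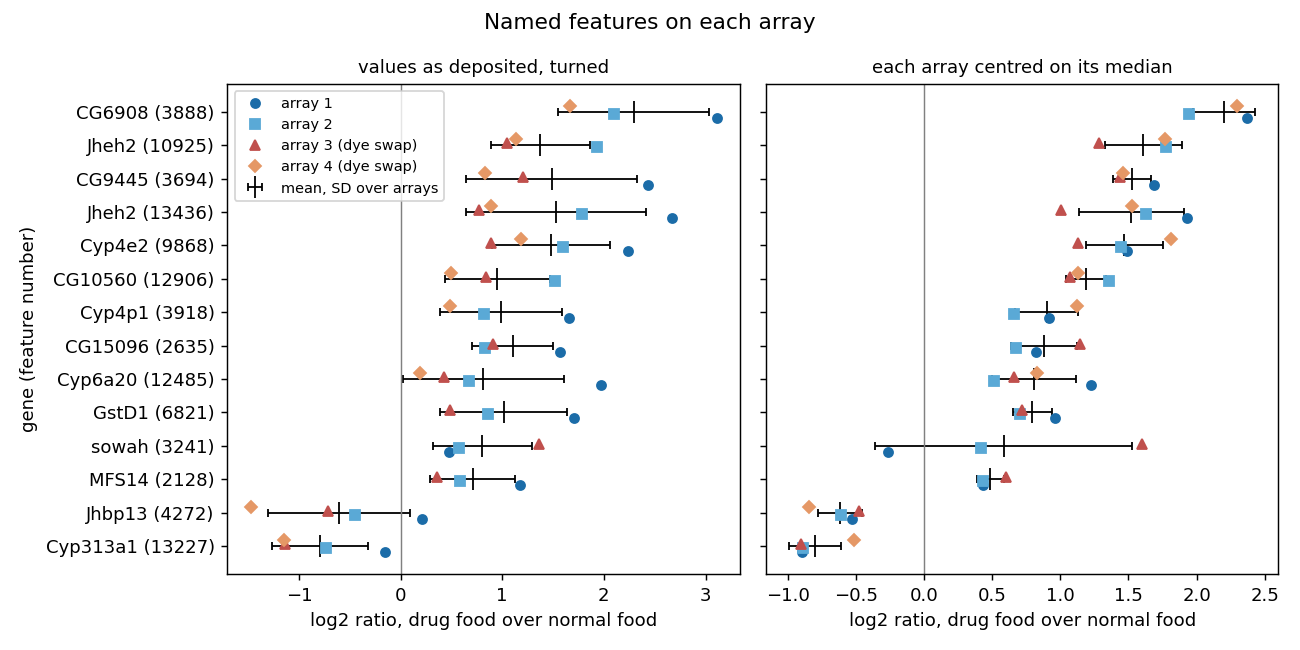
Log2 ratio of drug food over normal food on each array for the named features, on the deposited values (left) and with each array centred on its median (right); points are arrays, and the bar is the mean with the SD over arrays. CG6908 has the highest mean in both panels (2.29 and 2.20), and the SD over arrays is smaller after centring for every named feature except sowah.

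**Figure D2:**
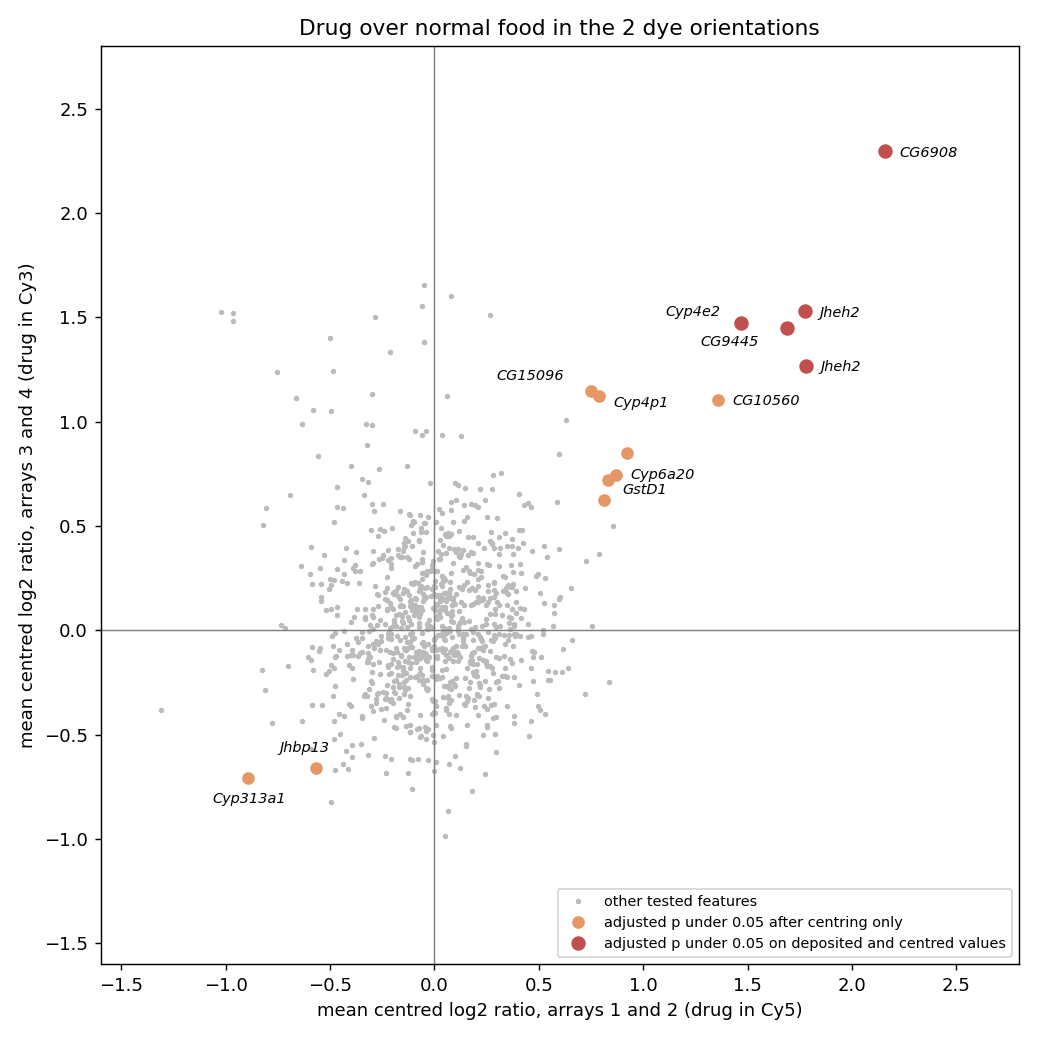
Mean centred log2 ratio of drug food over normal food on arrays 1 and 2 (horizontal) against arrays 3 and 4 (vertical), 1 point per tested feature (980 in all). The features higher after centring lie at or above 0.75 on the horizontal axis and 0.62 on the vertical axis, so the ratio was positive in both dye orientations under the reading used here.

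The gene lists were fixed before the data were examined, to ask which pathways of the head moved with the drug. Of the genes that passed, 2 of 4 on the deposited values and 6 of 11 after centring were in the lists of enzymes of foreign compound metabolism. These are the separate lists of P450 genes, of glutathione S-transferases, and of UDP-glycosyltransferases, esterases and epoxide hydrolases. They held 13 of the 515 measured genes. Joining these lists was chosen after their genes had been seen to pass, so the counts do not test such enzymes as a class. After centring 5 of the 6 genes were higher and Cyp313a1 was lower. The 6 include Jheh2, introduced above as an enzyme of juvenile hormone metabolism. Under the other reading of the columns 0 of the 13 passed, on the deposited values or after centring. Because the arrays have different offsets, the mean of a gene measured on 3 arrays depends on which array is missing, and for such genes the centred mean is given as well. Of 8 cytochrome P450 genes measured, Cyp4e2 passed on the deposited values. After centring Cyp4e2, Cyp4p1 and Cyp6a20 were higher and Cyp313a1 was lower, and the same 3 to 1 split held adjusted over the list alone on both sets of values. The other P450 genes did not pass, with ratios of 0.38 for Cyp6d4 (0.16 centred, n = 3), 0.09 for Cyp28d1, -0.08 for Cyp4d21 and 0.00025 for Cyp4ac1 (-0.02 centred). The value of Cyp6d4 joins 2 clones, 1 measured on array 1 and 1 on arrays 2 and 3. Of 3 glutathione S-transferases measured, GstD1 passed after centring, while GstE12 was at -0.24 ± 0.38 (SD, n = 4) and GstT4 at 0.05 ± 0.76 (SD, n = 4). Of the 2 measured genes among UDP-glycosyltransferases, esterases and epoxide hydrolases, Jheh2 passed and alpha-Est3, at 0.37 ± 0.46 (SD, n = 3; 0.16 centred), did not.

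As a group, the P450 genes had a median log2 ratio of 0.23, and cameraPR gave an adjusted p of 0.0589 over 8 lists. With an estimated correlation between genes the adjusted p was 0.905. After centring their median was 0.12, with an adjusted p of 0.0519, and 0.368 with an estimated correlation. Under the other reading of the columns the centred median was -0.02 (adjusted p = 0.839). Under the reading used here, the P450 median on the deposited values was 0.04, 0.41, 0.23 and 0.30 without arrays 1 to 4. The median of the other genes was -0.142, 0.113, 0.206 and 0.235, so without arrays 3 and 4 the P450 genes lay near it. The cameraPR adjusted p was 0.198, 0.0599, 0.128 and 0.133. No list passed on either set of values. At an unadjusted p under 0.05, cameraPR marked 3 lists on the deposited values and 1 after centring, and fry marked 0 on both.

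Genes of GABA and glutamate signalling (5 measured) had a median of -0.34 and did not pass as a list (cameraPR adjusted p = 0.0589, and 0.905 with an estimated correlation). After centring the median was -0.12 (adjusted p = 0.377). Gabat, the GABA transaminase, was at -0.49 ± 0.75 (SD, n = 4), the glutamine synthetase Gs2 at -0.34 ± 0.53 (SD, n = 4) and the glutamate dehydrogenase Gdh at -0.34 ± 0.43 (SD, n = 3; -0.12 centred). GluClalpha, a glutamate-gated chloride channel, was at 0.19 ± 0.55 (SD, n = 3; -0.03 centred). Photoreceptor genes (9 measured) had a median of -0.24, with the same adjusted p values, and of -0.25 after centring (adjusted p = 0.377). The scaffold gene inaD was at -0.58 ± 0.57 (SD, n = 3; -0.36 centred), the eye protein kinase C gene inaC at -0.53 ± 0.44 (SD, n = 3; -0.30 centred), chp at -0.44 ± 0.68 (SD, n = 4) and the arrestin gene Arr1 at 0.27 ± 0.79 (SD, n = 4). Under the other reading of the columns the centred medians of these lists were 0.09 and 0.13. Without array 2 both lists passed on the deposited values, with adjusted p of 0.0497 and 0.0352, but with an estimated correlation the adjusted p was 0.941 for both. Without arrays 1 to 4 the GABA and glutamate median was -0.34, -0.38, -0.24 and -0.09, and the photoreceptor median was -0.41, -0.24, -0.10 and -0.10. The median of the genes outside the photoreceptor list was -0.138, 0.127, 0.207 and 0.235. Without array 1, where that median was itself below 0, 0 of 9 photoreceptor genes and 0 of 5 GABA and glutamate genes were higher. The photoreceptor list then had a cameraPR adjusted p of 0.0828, and 0.71 with an estimated correlation.

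The 8 genes of cytosolic ribosomal proteins had a median of 0.07, the 11 of oxidative phosphorylation 0.06, the 7 of glycolysis and the citrate cycle 0.13, the 8 translation factors 0.18 and the 5 chemosensory genes 0.01. After centring the medians were 0.07, 0.04, -0.0071, 0.06 and -0.0015. The medians on the deposited values changed with the array left out. Without array 1 all were below 0, at -0.18, -0.19, -0.20, -0.11 and -0.19, and without array 4 all were above 0, at 0.34, 0.30, 0.21, 0.38 and 0.14. None of these lists passed cameraPR, with adjusted p from 0.478 to 0.942 on the deposited values. RpL23 was at 0.66 ± 0.39 (SD, n = 3; 0.44 centred), the elongation factor gene eEF1delta at 0.59 ± 0.66 (SD, n = 3; 0.37 centred), and the odorant-binding protein genes Obp56d and Obp57c at 0.40 ± 0.78 (SD, n = 4) and -0.40 ± 0.48 (SD, n = 3; -0.62 centred). Adjusted over the list alone, 1 chemosensory gene was higher and 2 were lower after centring, and none on the deposited values.

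Ion channels and synaptic genes were thinly covered. None of the 3 calcium channel genes on the array was measured on 3 arrays. Ca-beta had a value on array 2 alone and stj on arrays 1 and 3. Ca-alpha1D, the remaining one, had no value on any array, and no probe in the annotation used here was named for Ca-alpha1T or cac. The potassium channel gene Sh was at 0.35 ± 0.36 (SD, n = 3; 0.13 centred). The synaptic genes Sap47 and Rab3 were at 0.18 ± 0.58 (SD, n = 4) and 0.11 ± 0.29 (SD, n = 3), and Rab3 turned to -0.11 after centring. The neuropeptide genes Nplp1, Capa and AstC were at 0.27, 0.18 and 0.09 (0.05, 0.09 and -0.13 centred). Markers of muscle did not pass, with Act88F at -0.43 ± 0.89 (SD, n = 4). Nor did those of gut and reproductive tissue, which a head sample could hold as contamination. Amyrel was at 0.31 ± 1.14 (SD, n = 3; 0.09 centred) and ocn at 0.66 ± 0.27 (SD, n = 3; 0.44 centred). Outside the enzymes of foreign compound metabolism, 87 genes of the lists were measured. In limma's test 0 of them passed on the deposited values or after centring, and 0 and 15 had an unadjusted p under 0.05. Over all 515 genes, 15 and 74 had such a p.

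Under the reading used here, the swapped dyes gave each feature an effect of dye beside that of the drug. The fit of both to the deposited values again gave every feature the same variance. Its median dye effect over all 980 features was 0.39, so the offsets of the columns above 0 enter the dye effect of each feature. On the deposited values 31 features differed with the dye, all in 1 direction, but the count was 7, 389, 0 and 0 without arrays 1 to 4, and 156 of the 366 features measured on every array. In limma's test without arrays 3 and 4 in turn, 36.2% and 9.38% of features had an unadjusted p under 0.05. After centring 138 features had an unadjusted p under 0.05 for the dye, and 2 passed, the clones of Dus1 and CG6340. Their log2 dye effects were -1.24 and -1.27, with array 4 the only swapped array that measured them. Their drug ratios after centring were -0.14 and -0.17 and did not pass. A second clone of CG6340 had a centred drug ratio of 0.38. With a dye term beside the drug in limma's model, 7 features passed for the drug on the deposited values and 28 after centring, and all 5 of the first features were among both. The other reading of the columns exchanges the drug and dye effects.

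The arrays resembled each other more within a dye orientation than across. Over tested features, Pearson's r across features was 0.53 between arrays 1 and 2 and 0.42 between arrays 3 and 4. Across orientations it was 0.24, 0.15, 0.11 and 0.05, with a mean of 0.136. These are correlations over genes, which are not independent replicates, and they do not settle the orientation, because a shared dye effect and a shared drug effect change places between the readings. Of 22 genes with more than 1 tested clone, 12 had clones with the same sign after centring, and r between clones was 0.80, or 0.35 without Jheh2.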

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

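The search for arrays that lie apart was extended from the deposited to the centred values only after seeing the data, and no explanation is weighed in this part. For Cyp313a1, a cytochrome P450 gene, array 4 lay apart from the other arrays after centring, at -0.51 against -0.90, -0.89 and -0.90, so that its gap to the nearest array was 0.968 of the whole range. The translation factors had a median of 0.03 on array 1 after centring against 0.15, 0.16 and 0.14 on the other arrays, a gap of 0.846 of the range. Among 28 groups of 4 arrays tested in this way 2 stood out, and chance gives about 1 in 20. Dus1 and CG6340 differed between the dye orientations, with log2 dye effects of -1.24 and -1.27 in limma's fit of centred values (adjusted p = 0.0165 and 0.0148). Dus1 was at -0.76 and -1.17 on arrays 1 and 2 and at 1.52 on array 4, and CG6340 at -0.94 and -1.11 and at 1.52, and neither had a value on array 3.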

How the results depend on the processing

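Combinations with centring, the removal of the trend along the spots and the estimated correlation after centring, with the trend removed or without an array were added after seeing the data. The 5 features past limma's test became 14 after centring (12 higher, 2 lower), 11 after centring and scaling, 10 with array weights, 7 with a dye term and 7 on at least 2 arrays, 3 in a robust fit, 2 of 366 measured on all arrays and 32 under the other reading of the columns. The unmoderated test called 0 (21 at an unadjusted p under 0.05), where limma called 5 and SAM 4. It has 2 or 3 degrees of freedom per feature, and no cause of this difference was tested. The count was 4, 1, 3 and 5 without arrays 1 to 4, a range of 1 to 5. CG9445 lost its call without array 1, 2 or 3 (adjusted p 0.246, 0.187 and 0.117; ratios 1.01, 1.49 and 1.63), Cyp4e2 and the first Jheh2 clone without array 2 (0.187 for both; 1.44 and 1.45), and the second Jheh2 clone without array 2 or 3 (0.998 and 0.192; 1.09 and 1.54). CG9445 had no value on array 2, so its own values were unchanged there and that loss came from the other features in the fit. CG9445 also lost its call in SAM (q = 0.125) and in the robust fit (0.119), and the second Jheh2 clone in the robust fit (0.246) and on at least 2 arrays (0.0745). Under the other reading all but CG6908 lost it. With centring, it was 28 with a dye term, 22 with the trend removed, 13 on all 4 arrays (7 higher, 6 lower), 12 on at least 2 arrays, 2 in SAM, 0 in the unmoderated test (105 unadjusted), 0 under the other reading (86 unadjusted, limma), and 5, 23, 7 and 11 without arrays 1 to 4. All 5 features passed in every centred limma fit of the main reading that tested them, except 1 without array 1. Under the other reading after centring, CG9445 turned to -0.403, Cyp4e2 to -0.003 and the second Jheh2 clone to -0.428 (-0.085 without centring). CG6908 fell to 0.672 there (limma adjusted p = 0.888) and the first Jheh2 clone to 0.257. The number of lists past cameraPR stayed 0 except for 1, the P450 genes, with the trend removed (adjusted p = 0.0091, and 0.255 with an estimated correlation; 0.0519 to 0.949 under the other settings) and 2 without array 2, a range of 0 to 2, and was 0 with an estimated correlation whichever array was left out. Features with a dye effect went from 31 to 156 on all 4 arrays, 2 after centring, 63 with the trend removed, and 7, 389, 0 and 0 without arrays 1 to 4 (limma; 17.4%, 56.4%, 36.2% and 9.38% of tested features had an unadjusted p under 0.05). The causes of the other changes were not tested. Signal over background was not analysed here, and the few features measured on arrays 3 and 4 limit what could be tested.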

Other observations

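The tests of array offsets, of the trend along the spots, of dye bias with the pooled enzyme list, of a common shift and of the enzymes on few arrays were chosen only after the results were seen, and the sign patterns of the arrays were planned. Of the P450, glutathione S-transferase and glycosyltransferase, esterase or hydrolase genes, 48 features had values on 1 or 2 arrays and were not tested as features. Both clones of Cyp6d4 and a clone each of Cyp4ac1 and Cyp4d21 were among them and entered the gene averages tested above. Those named here were chosen after their values were seen. Relative to the median of each array, 25 of the 48 had a positive mean and 23 a negative one, with 5 above 1 and 5 below -1. Under the other reading of the columns 17 were positive and 31 negative, with 1 above 1 and 9 below -1. Cyp12d1-d was at 1.91 and 2.70 on arrays 3 and 4, the highest mean of 488 features measured on both, and Cyp6d5 followed at 1.61 and 1.75. Ugt37A1 was at 2.59 and Cyp6v1 at 1.05 on array 4. These 4 genes were measured in 1 dye orientation alone, so no swap balances their dye effect, and under the other reading each of their values is negative (-1.91 and -2.70 for Cyp12d1-d). Cyp9b1 was at 1.10 on array 1. The low ones were all measured on array 2 alone, with Cyp313a5 at -2.22, Cyp4c3 at -1.61, Cyp311a1 at -1.54, Cyp310a1 at -1.37 and Cyp4aa1 at -1.09.

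The first pattern is the set of clones higher with the drug. With the trend along the spots removed, 14 of the 14 clones called after centring still passed. The removal also raised the count of calls from 14 to 22, so passing alone says little. The ratios themselves stayed. Among the named clones higher after centring they ran from 0.80 (GstD1) to 2.20 (CG6908), and with the trend removed from 0.82 to 2.25 for the same 2 genes. For these clones, this argues against a smooth trend along the spots as the whole cause. For offsets between the arrays, 5 of the 5 clones still passed after centring, but this test could hardly have failed. The turned array medians had a mean of 0.00713, so centring hardly moves a ratio averaged over all arrays. It took the first Jheh2 clone from 1.531 to 1.523 and Cyp4e2 from 1.478 to 1.471. Centring also lowered the median standard error of the tested features from 0.357 to 0.148. The test therefore does not decide on offsets. Dye bias cannot be told apart from the drug effect, because columns turned before deposit would exchange them. After centring, 13 measured P450, glutathione S-transferase and epoxide hydrolase, esterase or glycosyltransferase genes pooled stood apart under the main reading (cameraPR p = 1.04e-05 with an estimated correlation, which came out at 0) and not under the other (p = 0.767), but on the deposited values the p was 0.206 with an estimated correlation. That list was formed after its genes had been seen to pass, so it does not test whether the drug may raise such enzymes as a class. The 48 features on few arrays had a median of 0.0752, at percentile 93.6 of 10000 random sets measured on the same arrays (17.2 under the other reading), which decides neither for nor against that hypothesis.

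The second pattern is that the count of features changed with the signs given to the arrays. The 4 arrays have 8 distinct sign patterns, too few for a share under 0.05. On the deposited values the real pattern gave 5 features and the highest other gave 32, which is the other reading of the columns, and 2 of the 8 gave at least as many as the real one. After centring the real pattern gave 14, the highest other 2, and 1 of the 8 gave as many. After centring, the pattern that is the other reading called 0 features in limma, with 86 at an unadjusted p under 0.05.

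The third pattern is that every deposited column had a median above 0. A shift of most transcripts with the drug and a dye offset left by the authors' normalization cannot be told apart as its cause, because the readings of the columns exchange them. The array medians of the tested features had a mean of 0.00713 ± 0.59 (SD, n = 4) under the reading used here and of 0.44 ± 0.29 (SD, n = 4) under the other, and turning the sign of 2 arrays gives the orientations opposite signs whenever all columns lie above 0, so the first value decides nothing.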
